A study of Mus musculus with 2 samples.

How the data were processed

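ATAC-seq was done on forebrain tissue from mouse embryos at 16.5 days, in 2 libraries that the labels number as biological replicates 1 and 2 of 1 group. Per the labels, fragments were made by Nextera tagmentation and the reads were placed on the mouse build mm10. The aligner, the peak caller, their versions, any shift of reads for the transposase and any filter on reads are not given in the sources used here. Depth is unknown, because the peak lists carry no read totals, and no value below was scaled by it.

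Each library came with 3 deposited lists made from its own alignments, per the listing deposited with it: peaks ranked by the irreproducible discovery rate (IDR), a lenient pseudoreplicated list and an IDR-thresholded list, all in the narrowPeak layout. Further lists were deposited over both replicates together. The lenient and thresholded lists also drew on another file whose type is not given in the sources used here. The deposited signal value per peak is the authors' own and was used only to rank or describe regions within a list. The deposited −log10 p and −log10 q per peak were used for a stricter setting and for ranking. The deposited score per peak, a whole number up to 1000, follows the IDR in the ranked list. In replicate 1, 68551 ranked peaks reached the lowest score of the thresholded list, which is an IDR of about 0.0501, and 68400 of them were the thresholded list. In replicate 2 the numbers were 75072 and 74932. The peaks left out included those off the main chromosomes, 41 and 31. Peaks were thus listed per library, and the thresholded list of each library was the main set. The ranked lists over both replicates were not used here, since it is not given whether they compare the replicates or pseudoreplicates.

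Peaks of a list that overlapped by at least 1 base were merged into 1 region, which kept the summit of the peak with the highest signal value. A region counted as found in the other library where the overlap covered at least 50% of either region. Regions were placed at random 100 times on their own chromosomes, with midpoints outside runs of unknown bases, and locations were read at summits, or at midpoints of placed regions. Genes were 21827 protein-coding genes of the GENCODE vM21 basic annotation of GRCm38, the assembly behind mm10, whose chromosome lengths fit the lists. A promoter was 1000 bases either side of a protein-coding transcript start. A gene had a promoter region in a library where a region lay at any of its starts, so the regions of both libraries could differ. A gene's domain ran to the midpoints between its starts and the neighbouring starts, up to 500000 bases on each side.

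The 23 gene lists, with 349 genes that all matched the annotation, and the 22 consensus sites were fixed before the data were examined. Lists were compared with 10000 random lists of the same size by a two-sided permutation test, with Benjamini-Hochberg adjustment over the 23 lists and a threshold of 0.05. For promoters, random genes were matched in 5 bins of the CpG ratio and 3 bins of window length. For distal regions they were matched in 10 bins of domain length, and counts entered as log2(count + 1). The contrast of forebrain and posterior genes used 100000 permutations of list membership. Its expected size under matching on domain length was taken from the means of the matched lists, weighted by list size, after the contrast had been seen. Genes are not replicates, so these p-values describe the 2 libraries and not a population of embryos. Random genes were drawn singly from the whole genome. For genes that lie in clusters, whose calls may depend on each other, the p-values may thus be too small. Consensus sites were counted on both strands and compared with 10 dinucleotide-shuffled copies of each sequence. Intervals of shares are exact 95% binomial intervals and cover counting error only.

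The genes named in the text followed a rule set at the same time. In each list these were the 2 genes with most distal regions, the 2 with the highest promoter signal in the lower of both libraries, and up to 3 in alphabetical order without a promoter region in either. Over all genes they were the 10 with most distal regions and the 10 with the highest promoter signal. Called members of lists and families with 5 or fewer called promoters were named as well, outside that rule and after their values were seen.

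The procedures were tested on simulated data. The overlap rule found 70.2% of 27212 simulated regions where 70.2% had been copied. Random lists of 16 genes passed the unadjusted threshold of 0.05 in 2% of trials for promoters and 3% for distal regions. Lists with every promoter closed, or with regions added to each gene, passed in 100% of trials, over 21827 genes. These are large effects, so the trials do not show how often smaller ones would pass. Shuffled list membership passed in 4.5% of trials of the contrast over its 77 genes. The site search found the CTCF core in 21% of 3000 sequences where 21% had been given it.

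Alternatives fixed beforehand were a −log10 q of at least 5, the lenient lists, overlap of 1 base or of 50% of both regions, promoter windows of 500 and 2000 bases, and distal from 5000 bases. Others were every peak counted without merging, Fisher's exact test without matching, and matching on CpG as well. The contrast was also taken in counts per 100 kb and without the posterior Hox list. Further ones were 50 bases around summits, flanking sequence 1000 bases away as background, either replicate left out, and the lists over both replicates. Regions were compared with the mitochondrial genome by blastn, at 100 bases and 95% identity or more. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and pysam 0.24.0, samtools 1.23.1 and BLAST 2.17.0.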

Results

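Open chromatin was mapped in the forebrain of mouse embryos by ATAC-seq, the assay for transposase-accessible chromatin, in which a transposase inserts sequencing adapters into DNA that is not wrapped in nucleosomes. The tissue came from B6NCrl embryos of both sexes at 16.5 days of gestation, a stage at which cortical neurons are still being born from radial glia. The series held 1 group with 2 biological replicates, each a pool of embryos, with 41 embryos for replicate 2 and a number not given for replicate 1. With 1 group there was no condition to test, so the libraries were described and compared with each other, and gene lists fixed beforehand were compared with matched genes. The files held peak lists without read totals, so the depth of each library is unknown.

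The first comparison asked how many open regions each library gave and how many of them the other library also gave. After overlapping peaks were merged, replicate 1 had 27502 regions covering 25.8 Mb, with a median width of 922 bases. Replicate 2 had 32629 regions covering 28.4 Mb, with a median width of 846 bases. Chromosome X held 737 regions in replicate 1 and 807 in replicate 2, and chromosome Y held 12 and 9. Of the regions of replicate 1, 24559 (89.3%, exact 95% interval 88.9% to 89.7%) were found in replicate 2. Of the regions of replicate 2, 24601 (75.4%, exact 95% interval 74.9% to 75.9%) were found in replicate 1. Random placement of the other library's regions gave means of 1.44% and 1.22%, and at most 1.60% and 1.34% in 100 placements. The intervals cover counting error only.

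Regions found in both libraries were stronger and lay at promoters more often than the rest. The median signal value was 9.07 for the shared and 6.32 for the other regions of replicate 1, and 10.98 and 7.06 in replicate 2. In replicate 1, promoters took 44.9% of the regions found in both libraries and 9.65% of the 2943 others. In replicate 2 the values were 45.1% and 9.74% of 8028 others. Sharing followed strength, ranked within each library by the authors' signal value. It went from 72.7% of the weakest 2751 regions of replicate 1 to 100% of its strongest 2750. In replicate 2 it went from 42.9% of the weakest 3263 regions to 99.9% of the strongest 3262. Signal values are the authors' own per-peak values and serve here only to rank or describe regions within a list.

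**Figure D1:**
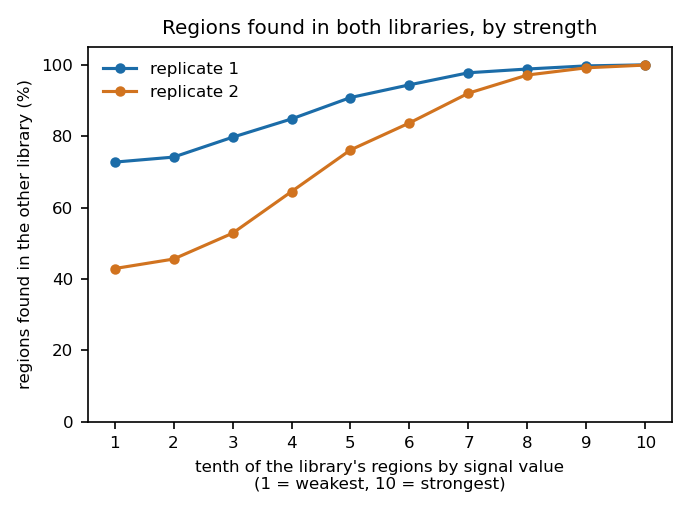
Percentage of each library's regions that the other library shared (y axis), in 10 equal groups ranked by the authors' signal value from weakest to strongest (x axis), with 1 line per replicate. Replicate 2 starts lower, at 42.9% against 72.7%, and both lines end near 100%.

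Promoters, taken as positions within 1000 bases of a protein-coding transcript start, held far more regions than random placement gave. They took 38.8% ± 3.35 (SD, n = 2) of the region summits, 41.1% in replicate 1 and 36.4% in replicate 2. These were 19.2 and 16.9 times the mean of 100 random placements, which reached at most 2.32%. Introns took 28.3% and 31.7% of summits in the respective libraries, against 42.9% and 43.0% at random. Stretches between genes took 27.5% and 28.6%, against 51.3% and 51.2% at random, and exons took 3.16% and 3.37%, against 3.65% and 3.66%. The share depended on which list was read: with the lenient (pseudoreplicated) lists, which hold weaker regions, 19.5% of summits lay at promoters.

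Of 21827 protein-coding genes, 11786 (54.0%) had a promoter region in both libraries. The 10 genes with the highest promoter signal included Zfp960, a zinc finger gene (chromosome 17, 17064113 to 17089628, mm10), at 30.5 in replicate 1 and 30.6 in replicate 2. They also included Iars, which encodes the cytoplasmic isoleucyl-tRNA synthetase, at 28.3 and 30.9, Depdc1a at 28.3 and 31.2, Hltf, a DNA helicase of the SWI/SNF family, at 26.8 and 29.1, and the imprinted gene Zim1 at 26.2 and 29.7. Cep128 and Tshr share a start region and so a single value, 29.6 and 30.6. The other 3 were Cfdp1 at 27.6 and 30.6, Tmem218 at 26.8 and 29.5, and 6720489N17Rik at 27.8 and 31.1.

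The next comparison asked which of 23 gene lists, covering the cell types of the forebrain and of other tissues, had promoter regions in both libraries more or less often than genes of like CpG content. In a permutation test against 10000 matched random lists, 0 lists had more called promoters and 6 had fewer after Benjamini-Hochberg adjustment over the 23 lists. At an unadjusted p under 0.05 there were 7, the added one being the pan-neuronal list. The smallest p the random lists could give was 0.0002 before adjustment, which is 0.0023 for promoters and 0.00092 for distal regions after it.

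Promoters of genes that pattern more posterior parts of the neural tube were rarely called. None of the 17 posterior Hox genes, which specify the trunk and tail, had a promoter region in either library, where matched lists gave 78.0% ± 8.94 (SD over random lists), adjusted permutation p = 0.0023. Examples are Hoxa10, Hoxa11 and Hoxa13. Hox genes lie in clusters and the random genes did not, so the 17 are not independent and this p may be too small. Of the 20 midbrain, hindbrain and spinal cord genes, 1 had a promoter region in both libraries, against 75.5% in matched lists, adjusted permutation p = 0.0023. That gene was Atoh1, a proneural gene of the hindbrain, with a region at chromosome 6, 64728608 to 64729903 (mm10, replicate 1) and a signal of 5.66 in replicate 1 and 4.95 in replicate 2. En1, which marks the boundary of midbrain and hindbrain, Evx1 and Barhl1 had none in either library. With the lenient lists En1 had a promoter region in both libraries, while Evx1 and Barhl1 did not. The thalamus and hypothalamus list stands for parts of the forebrain itself, behind the cortex and striatum, and not for posterior parts. It had 4 of 14, against 73.6%, adjusted permutation p = 0.00307, and 0.105 by Fisher's exact test without matching. Its 4 members were Tcf7l2, Lhx9, Sim1 and Pitx2. Avp, the vasopressin gene, Fezf1 and Foxb1 had none.

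Lists of endothelial, choroid plexus and epidermal genes also had fewer called promoters than matched lists. Endothelial genes had 3 of 16, against 59.8% in matched lists, adjusted permutation p = 0.00345. The 3 were Slc2a1, the glucose transporter of the blood-brain barrier, Mfsd2a and Lef1, while Cldn5, Cdh5 and Emcn had none in either library. At Lef1 the strongest promoter regions of both libraries did not overlap. Choroid plexus and ependyma genes had 3 of 12 (Foxj1, the regulator of motile cilia, Rsph1 and Msx1), against 56.6%, adjusted permutation p = 0.0414. Epidermis genes had 0 of 13 in both libraries, against 29.9%, adjusted permutation p = 0.00644, although Lor and Perp had a region in replicate 1 and Krt10 in replicate 2. The epidermis call was lost without replicate 1 (adjusted permutation p = 0.059) and without replicate 2 (0.339), and the choroid plexus call without replicate 1 (0.4). In the thresholded and conservative lists over both replicates, both calls were lost as well (choroid plexus 1 and 0.706, epidermis 0.718 and 0.731), and choroid plexus also by Fisher's exact test (0.119) and epidermis with a window of 2000 bases (0.0821). With the lenient lists both were lost, and so was the endothelial call (adjusted permutation p = 0.177), which left 3 lists.

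The remaining lists did not pass the threshold. Pan-neuronal genes had 15 of 16 promoters called, against 70.3% in matched lists, adjusted permutation p = 0.0683. The list passed as more often called with replicate 1 left out (adjusted permutation p = 0.0147), but not with replicate 2 left out (0.105). It also passed with a window of 500 bases (0.0449) and in the thresholded and conservative lists over both replicates (0.0497 and 0.0423). By Fisher's exact test without matching it passed as well (0.00346). Syt1, which encodes a calcium sensor of synaptic vesicles, had the highest signal of the list, 21.8 and 22.7, with 99.4% and 98.5% of each library's regions at or below it, followed by Nrxn1 at 15.7 and 18.2. All 14 immediate early genes and 15 of 16 housekeeping genes had a promoter region, as did 18 of 20 radial glia genes and 17 of 20 pallial glutamatergic genes. In the pallial list the deep-layer gene Tle4 had promoter signals of 14.2 and 15.1. Slc17a6 and Slc17a7, which encode vesicular glutamate transporters, had no promoter region in either library. The subpallial GABAergic list had 14 of 20. In either library 4 of its genes had no promoter region, of which the alphabetical rule names Lhx6, Lhx8 and Nkx2-1. Intermediate progenitor genes had 9 of 12, and Eomes, their best known marker, had no promoter region in the thresholded list of either library. The difference of this list from matched lists was -2.44 percentage points. With the lenient lists it was 12.5 (adjusted permutation p = 0.49), so absence from the thresholded lists does not show a closed promoter. Cajal-Retzius genes had 6 of 11, signalling and morphogen genes 9 of 16, and mature neuron genes 6 of 14. Mural and meningeal genes had 5 of 14 (Kcnj8, Foxc1, Foxd1, Tbx18 and Twist1), astrocyte genes 4 of 12 (Aldh1l1, Gja1, Slc1a2 and Aldoc) and oligodendrocyte genes 4 of 13 (Olig1, Olig2, Pdgfra and Myrf). Microglia genes had 2 of 16 (Irf8 and Sall1), erythroid genes 2 of 13 (Klf1 and Epor), liver genes 1 of 15 (Apob) and muscle genes 1 of 15 (Myh7). With a window of 500 bases erythroid and muscle genes passed as less often called, by -19.7 and -21.5 percentage points (adjusted permutation p = 0.046 and 0.0429).

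**Figure D2:**
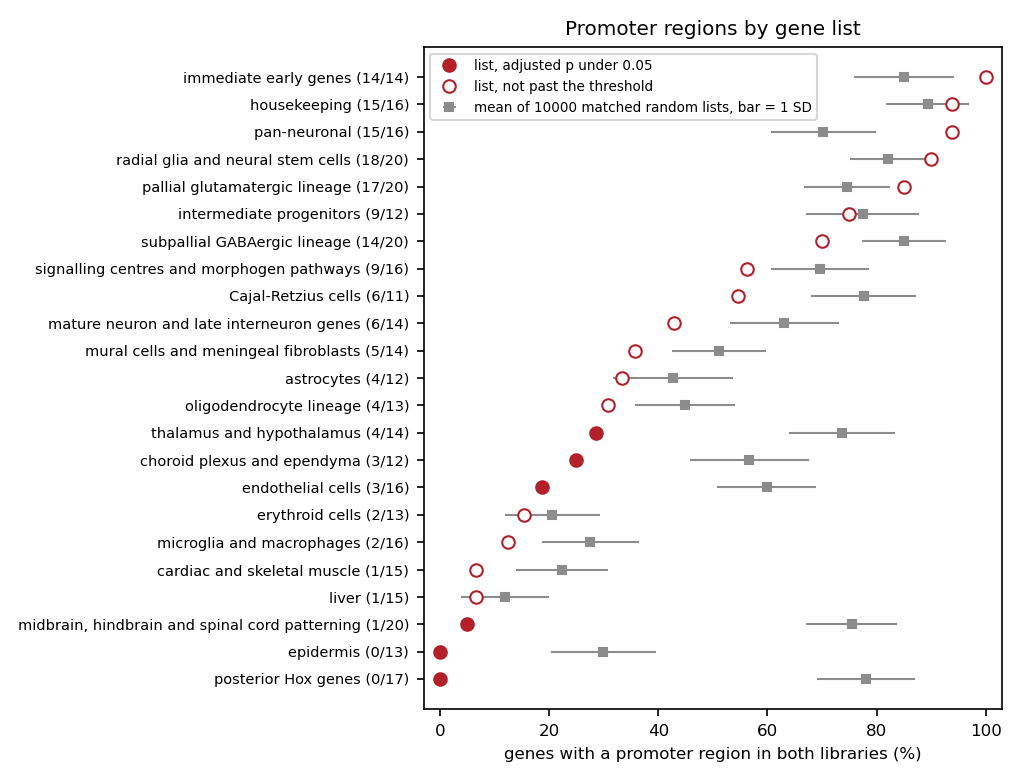
Percentage of each list's genes with a promoter region in both libraries (x axis; circles, with counts beside the list names on the y axis) against the mean of 10000 matched random lists (squares; bars, 1 SD). The 6 filled circles passed the threshold and all lie left of their squares, from 28.6% for thalamus and hypothalamus down to 0% for posterior Hox and epidermis.

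Distal regions, over 1000 bases from every protein-coding start, were counted for the gene with the nearest start. Of the 24559 regions of replicate 1 shared with replicate 2, 13309 (54.2%) were distal, and 6047 genes had at least 1 within 500000 bases. Of the 10 genes with the most, Celf4, an RNA-binding protein of neurons, had 22, Auts2, a regulator of brain development, 19, and Myt1l, a neuronal transcription factor, 18. The synaptic genes Dlg2 and Nrxn3 had 17 each. Pde4d, Ubash3b, the corepressor gene Tle3 and the predicted gene Gm26897 had 16 each, and the homeobox gene Pbx1 had 15. Counts at single genes, here and below, were not scaled by domain length, which was 793 kb for Celf4, 1649 kb for Auts2 and 1835 kb for Dlg2. Per 100 kb of domain these genes had 2.77, 1.15 and 0.926 regions. The nearest start is a rule of assignment and does not show which gene a region acts on.

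Against random lists matched on the length of the gene's domain, 7 of the 23 lists had more distal regions and 0 had fewer. This is by the adjusted permutation p, and the same number passed unadjusted. Lists with short domains had little room for fewer: posterior Hox genes had 0 regions, at an adjusted permutation p of 0.626. Radial glia genes stood highest, with 100 regions over 20 genes and a mean log2(count + 1) 1.25 above matched lists, adjusted permutation p = 0.00092. Nfib, a nuclear factor I gene of glial and progenitor development, had 13 and Sox2, the stem cell factor, 11. Pallial glutamatergic genes had 70 regions, 0.95 above matched lists on the log2 scale, adjusted permutation p = 0.00092, with 7 at Sox5, another deep-layer gene, and 6 at Tle4. Subpallial genes had 50, 0.62 above, adjusted permutation p = 0.00307, with 9 at Isl1, a striatal lineage factor, and 7 at Meis2. Intermediate progenitor genes had 27, 0.85 above, adjusted permutation p = 0.00092, with 8 at Insm1 and 4 at Neurog2. Eomes, without a promoter region, had 2. Pan-neuronal genes had 80, 0.84 above, adjusted permutation p = 0.00092; Celf4 and Myt1l gave 22 and 18 of them.

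Immediate early genes, which neuronal activity induces, had 27 distal regions and at least 1 at each of the 14 genes, 0.90 above matched lists, adjusted permutation p = 0.00092, led by Egr3 and Ier2 with 4 each. Signalling and morphogen genes had 35, 0.66 above, adjusted permutation p = 0.00591, with 6 at Gli3 and 5 at Wnt7b. All 7 lists stayed past the threshold when either replicate was left out.

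For the 16 lists not past the threshold, differences from matched lists ran from -0.25 for mural and meningeal genes to 0.35 for choroid plexus genes on the log2 scale. Their distal regions numbered 18 for mature neuron genes, 18 for endothelial, 17 for thalamic and hypothalamic, 16 for Cajal-Retzius, 15 for midbrain, hindbrain and spinal cord, 14 for astrocyte and 14 for choroid plexus genes. Microglia genes had 13, of which Ptprc, a leukocyte gene without a promoter region, had 8. Mural and meningeal genes had 10, oligodendrocyte genes 9, epidermis genes 6, muscle genes 5, housekeeping genes 5, liver genes 4, erythroid genes 2 and posterior Hox genes 0. The oligodendrocyte list passed in the lenient lists and in both lists over the replicates together, with an excess of 0.53 to 0.83 on the log2 scale.

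**Figure D3:**
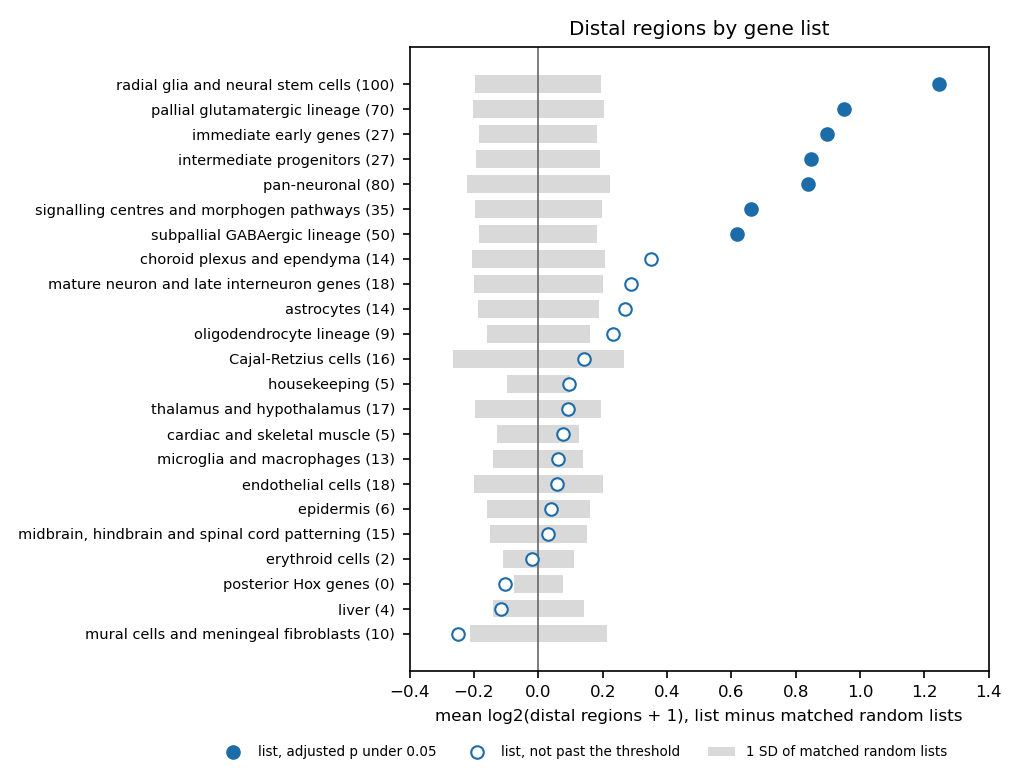
Mean log2(distal regions + 1) of each list minus the mean of its matched random lists (x axis), with the number of regions beside each list name (y axis); grey bars span 1 SD of the random lists on each side. The 7 filled circles passed the threshold and range from 0.62 for subpallial genes to 1.25 for radial glia genes.

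The sample itself implied a contrast between genes of the pallial and subpallial lineages, called forebrain genes here, and genes that pattern more posterior parts. The 40 genes of the pallial and subpallial lists had a mean of 3 distal regions (SD 2.3), and the 37 posterior genes had 0.41 (SD 0.93). The difference in mean log2(count + 1) was 1.41, permutation p = 1e-05, two-sided and the smallest the resamples could give. Lists matched on domain length gave a difference of 0.59, which left 0.81 above it. The midbrain, hindbrain and spinal cord list did not differ from its matched lists (0.029, adjusted permutation p = 0.884). For posterior Hox genes (-0.10, adjusted permutation p = 0.626) the test could not show fewer, since they had 0 regions and their matched lists few. Of the forebrain genes 6 had no distal region, against 29 of the posterior genes, and 31 had a promoter region in both libraries, against 1. Hox genes lie in clusters, and the median domain of posterior genes was shorter, 33.9 kb against 188.4 kb. Per 100 kb of domain the means were 1.27 and 0.21 regions, permutation p = 1e-05. Without the posterior Hox list the difference was 1.14, permutation p = 5e-05. The other posterior list still held Hoxa2, Hoxb2, Hoxa3, Hoxb4 and Hoxb1.

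Sequence at the distal summits was searched for 22 consensus sites of transcription factors fixed beforehand, within 100 bases either side. The summits were those of regions that the other library shared, so both libraries gave mostly the same places in the genome. The SDs between libraries thus do not measure the spread between independent samples. In both libraries 13 sites were more frequent than in dinucleotide-shuffled copies and 4 were less frequent, by intervals from exact bounds. The CTCF core, the site of the insulator protein, was 34.5 ± 2.21 times as frequent (SD, n = 2), and lay at 4.46% and 4.57% of summits. The TAATTA core was at 10.2% and 10.4% of summits, 4.61 ± 0.0212 times shuffled (SD, n = 2), and the extended LHX form was 5.16 ± 0.122 times (SD, n = 2). The POU octamer ATGCAAAT reached 4.53 ± 0.219, MEF2 sites 4.57 ± 0.134 and RFX sites 4.11 ± 0.0947 (SD, n = 2 each). NRF1 sites reached 13.7 ± 0.742 (SD, n = 2), from 25 summits in replicate 1, and ETS sites 2.56 ± 0.145 (SD, n = 2).

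The other sites above shuffled sequence had lower ratios. The proneural E-box CAGATG lay at 25.1% and 25.2% of summits, 1.65 ± 0.0177 times shuffled (SD, n = 2). MEIS sites reached 1.72, the CAGCTG E-box 1.35, SOX sites 1.28 and single NFI sites 1.27 times as means of both libraries. With flanking sequence as background the SOX site was no longer separated (1.04 times). Ratios of other sites also depended on the setting. Against flanking sequence the TAATTA core was at 1.64 times, the LHX form at 1.96, MEF2 at 2.16, GATA at 0.394, the CAGCTG E-box at 2.47 and single NFI sites at 2.35. NRF1 was at 7.42 times within 50 bases of summits, and with the lenient lists ETS was at 1.56 and HNF4 at 0.567. Of the 4 control sites of blood and liver factors, 2 were less frequent than in shuffled copies, GATA at 0.646 and HNF4 at 0.357 times, as were the T-box site at 0.6 and the P53 site at 0.763. Within 50 bases of summits, GATA (0.708), HNF4 (0.594) and P53 (0.789) were no longer separated. AP-1, the blood factor site PU.1 and the NFI palindrome, at 0.954, 1.15 and 2.05 times, were separated from shuffled sequence in neither library. With the lenient lists PU.1 (1.19 times), the NFI palindrome (2.86) and TEAD (1.15) were more frequent than shuffled. With flanking sequence as background the palindrome reached 9.25 times. In the main lists it lay at 13 summits in replicate 1 and 12 in replicate 2, so that ratio rests on few sites. The TEAD site, at 1.1 times, was separated in replicate 2 alone, with an interval of 1.01 to 1.22. With all distal regions of 1 library, the TEAD site was more frequent than shuffled without replicate 1 (1.13 times) and the NFI palindrome without replicate 2 (2.81 times). The HNF1 site was at 0 of 13309 summits in replicate 1, and its background was too rare for a ratio to be read. A consensus match does not show that a factor was bound.

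**Figure D4:**
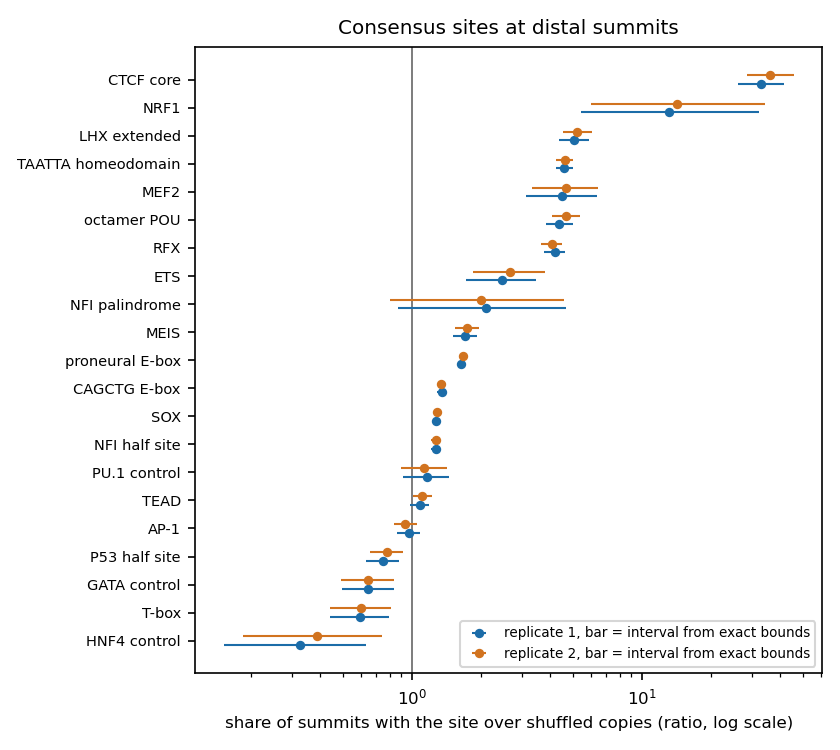
Share of distal summits with each consensus site over the share in shuffled copies (x axis, log scale), for each site but HNF1 (y axis), with 1 point per replicate and bars for the interval from exact bounds. The CTCF core stands at 34.5 on average and HNF4 at 0.357, and the bars of both replicates overlap at each site shown. The summits of both replicates come from shared regions, so this overlap is not independent evidence.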

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

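The ranked lists, which the comparisons did not use, held entries on assembled sequences outside chromosomes 1 to 19, X and Y: 95 entries in replicate 1 and 75 in replicate 2. They were singled out as a signal in data outside the main measurement. These entries lay on 15 and 14 sequences, with a highest signal value of 29.8 and 31.3, and none was on the mitochondrial genome. The lenient and thresholded lists had 0 such entries.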

How the results depend on the processing

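No alternative was chosen after a result was seen. The 7 lists with more distal regions passed under all 10 alternatives of that test, the contrast of forebrain and posterior genes kept its direction, with differences of 1.14 to 2.35 on the log2 scale, and 13 to 16 sites were more frequent than in the background. With flanking sequence the 13 were not all the same, as SOX was lost and the NFI palindrome gained, so that 12 of the main ones held. The palindrome was at 9.25 times there, from 13 and 12 summits in replicates 1 and 2. Promoter shares were 36.4% to 41.1% with either replicate left out. Where values moved or changed sign, the cause was not tested unless the alternative itself fixes it, as with longer lists. No list difference below that changed sign had passed the threshold of the same test in the main setting. Values for lists are percentage points called above matched lists for promoters, and differences in mean log2 count for distal regions.

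With the lenient lists there were 70616 regions in replicate 1 and 78948 in replicate 2, of which 85.3% and 76.0% were shared. The gain in sharing from the weakest to the strongest group was 46.3 and 61.6 percentage points, promoters took 19.5% of summits, 3 lists passed for promoters, and the 16 sites included PU.1, the NFI palindrome and TEAD anew. Promoter differences changed sign to 1.0 for subpallial, 12.5 for intermediate progenitor, 0.68 for oligodendrocyte, 21.9 for astrocyte, 0.909 for microglia, 12.8 for mural and 2.39 for erythroid genes. Distal differences changed sign to -0.051 for endothelial, 0.18 for mural, 0.081 for erythroid and -0.053 for epidermis genes. Without merging there were 68400 and 74932 peaks, which follows from counting several summits per region. At a −log10 q of at least 5 the gain in replicate 1 was 25.5. With overlap of 50% of both regions, 86.5% and 72.9% were shared, the gains were 34.7 and 63.0, and distal differences were -0.12 for Cajal-Retzius and -0.026 for epidermis genes.

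In the thresholded list over both replicates promoters took 28.9% of summits, and promoter differences were 7.27 for intermediate progenitor, 2.93 for oligodendrocyte, 16.8 for astrocyte, 7.82 for mural, 4.53 for erythroid and 1.44 for mature neuron genes, with distal differences of -0.018 for endothelial and -0.0098 for epidermis genes. In the conservative list promoters took 29.9%, and the promoter differences were 7.64 for intermediate progenitor, 17.4 for astrocyte, 5.23 for erythroid, 3.49 for liver and 1.87 for mature neuron genes, with a distal difference of -0.033 for housekeeping genes. A promoter window of 2000 bases gave 6.58 for liver genes. Fisher's exact test without matching passed 13 lists, of which 5 had more called promoters (pallial, radial glia, pan-neuronal, housekeeping and immediate early genes) and 8 fewer, microglia, erythroid, liver and muscle genes anew, and gave 16.02 for subpallial, 21.0 for intermediate progenitor, 0.548 for Cajal-Retzius and 2.25 for signalling genes. With 1 replicate left out, promoter differences ranged from -3.64 to 10.9 for intermediate progenitor, -10.7 to 12.1 for astrocyte and -16.2 to 3.36 for mural genes, and the distal difference from -0.042 to 0.023 for erythroid genes. Distal regions from 5000 bases gave -0.084 for epidermis genes, and matching on CpG ratio as well gave -0.053 for Cajal-Retzius, -0.019 for thalamic and hypothalamic and -0.031 for midbrain, hindbrain and spinal cord genes. For sites, 50 bases around summits gave a ratio of 1.02 for AP-1, and flanking sequence gave 1.02 for AP-1, 0.811 for PU.1 and 1.01 for the P53 site, which was less frequent than shuffled sequence in the main setting. Among single lists and sites, 17 combinations of a result with an alternative were no longer past their threshold, and 24 passed it anew. The same list or site can count under several alternatives, and changes of sign were counted apart. Depth, which is unknown, limits which weak regions could be called in either library.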

Other observations

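The tests on regions found in 1 library only, on the 2 regions with the highest −log10 p and on the promoter regions ranked beside them were chosen after the results were seen. Gene families named by their symbols were chosen after the gene lists had been tested, and the genes named from them, those with most regions or in counts of 5 or fewer, after their values were seen. In permutation tests like those of the lists, 21 of 26 families passed the adjusted threshold for promoters or distal regions. For promoters, random genes were drawn with replacement here, and without it for the lists. Some families, such as Hox, keratin, T-box and Sox, share members with the gene lists. Where the genes of a family lie in clusters, as Hox genes and clustered protocadherins do, the p-values may be too small. Sensory receptor families had the lowest shares beside Hox and keratin genes: 4 of 1133 olfactory receptor genes (Olfr452, Olfr459, Olfr658 and Olfr94) had a promoter region in both libraries, against 7.14% in matched lists, and 1 of 330 vomeronasal receptor genes (Vmn1r4), against 2.62% (adjusted permutation p = 0.000743 and 0.00416). Of the transcription factor families in development, 6 had fewer called promoters than matched genes. Of 39 Hox genes 0 had one, against 73.9%, and the LIM homeobox family had 2 of 8 (Lhx2 and Lhx9) against 86.5%, the T-box family 6 of 18 against 64.5%, Irx 2 of 6 (Irx2 and Irx5) against 87.8%, Forkhead 20 of 44 against 75.7% and Sox 11 of 19 against 83.4%. Zic, with 4 of 5 (all but Zic4) against 86.9%, and POU, with 7 of 16 against 66.7% (adjusted permutation p = 0.051), did not pass. Clustered protocadherins had 4 of 56 (Pcdhac1, Pcdhac2, Pcdhgc3 and Pcdhgc4), against 53.7%, adjusted permutation p = 0.000743. More promoters than in matched genes were called in 5 families: 75 of 78 mitochondrial ribosomal proteins, 76 of 79 ribosomal proteins, 38 of 40 proteasome subunits, 55 of 58 cilium and centrosome proteins and 324 of 394 zinc finger genes. Histone genes, with 61 of 67, did not pass (adjusted permutation p = 0.155).

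More distal regions than in matched genes were found at 6 families and fewer at 3. Slit and Robo genes had 28 regions over 7 genes, 11 of them at Robo1, and lay 0.85 above matched lists on the log2 scale (adjusted permutation p = 0.0379). Semaphorins and plexins had 60 over 29 genes, with 11 at Plxna2 (0.45 above, adjusted permutation p = 0.0114), and ephrins and Eph receptors 47 over 22, with 8 at Epha3 (0.41 above, adjusted permutation p = 0.0445). Sox genes had 66 over 19 genes, 12 of them at Sox4 and 11 at Sox11, 0.70 above matched lists (adjusted permutation p = 0.0026). Voltage-gated potassium channels had 47 over 30 genes (0.40 above, adjusted permutation p = 0.0295) and histone genes 8 over 67 (0.067 above, adjusted permutation p = 0.0445). The families with fewer were olfactory receptors (-0.11), vomeronasal receptors (-0.30) and cytochrome P450 enzymes (-0.21), each at an adjusted permutation p of 0.00173. Chromosome X held 4.51 regions per Mb in replicate 1 and 4.94 in replicate 2, below the lowest autosome, chromosome 14, at 8.98 and 10.7.

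Promoters of posterior genes without a region are the first pattern. If they were only too weak for the reproducibility threshold, the lenient lists should hold them at a rate of at least 50% of that of matched genes. They held 8 of the 37 (21.6%), against 87.1% ± 4.51 (SD over random lists), which argues against the threshold as the whole cause. However, 7 of the 8, En1 among them, belonged to the midbrain, hindbrain and spinal cord list. A closed state of the posterior promoters in forebrain cells may remain, and with 1 tissue in the series no biological explanation was tested.

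The second pattern is that the regions with the highest −log10 p were not all promoters. In both libraries the top region lay between genes at chromosome 12, 97061368 to 97061856 (mm10), with a −log10 p of 4832 and 4676, and the next at chromosome 2, 22589144 to 22590226 in replicate 1, over pseudogenes Gm13339 and Gm13340 within Myo3a. Reads from mitochondrial DNA placed on nuclear copies of it are a candidate explanation, since both regions matched the mitochondrial genome, 2 of 2, over 365 bases at 99.7% identity and, in replicate 1, 1084 bases at 98.3%, while 0.04% and 0.0337% of all regions did. Among the 10 highest, 3 matched in each library, between the bounds of 1 and 5 set beforehand, so that test left the whole group open, and by signal value 5 and 4 of the 10 highest matched. Of the 7 promoter regions among them, at Pja2, Xpo1 and Cldnd1 for example, 0 matched, so this source does not account for those, and no biological explanation was tested.

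The third pattern is the regions found in 1 library only, 2943 in replicate 1 and 8028 in replicate 2. The reproducibility threshold is a candidate cause: 95.3% and 94.3% of them overlapped the other library's lenient list, against at most 3.13% and 2.72% when placed at random. Of the rest, 137 and 445 overlapped no region of the other library's ranked list. A difference in depth, which is unknown, and a difference between the pools of embryos stay open and were not tested.

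The excess of distal regions at immediate early genes was also tested against their CpG-rich promoters. Under matching on CpG ratio and domain length the excess was 0.79 on the log2 scale, against 0.90 without CpG, adjusted permutation p = 0.00115. CpG content thus did not account for it. Whether these regions may reflect activity in the embryo or handling of the tissue was not tested.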
